A study of Mus musculus with 6 samples.

How the data were processed

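Polyadenylated RNA of mouse podocytes was sequenced by the authors in 6 libraries, 3 labelled KO and 3 labelled WT control. Per the file headers, the authors' tables use the Ensembl 67 annotation of the mouse build NCBIM37, flattened into 368092 exonic parts, with overlapping genes joined into 908 aggregate identifiers. The submitters' processing notes name TopHat 1.4.1 and GRCh37, a human build, which goes against the mouse build in the file headers; coordinates are given here as the files give them. The tool that counted the reads and its strand setting are not given in the sources used here. Each deposited table gives, for each part, the raw read count, the number of bases covered, the length, and the covered fraction, which equals covered bases over length. Of 62 pairs of parts on opposite strands that share at least 90% of their bases, 61 had counts within 10% of each other, so the counts were treated as unstranded, and reads of a gene and its antisense partner cannot be told apart. All 43 mitochondrial parts had 0 counts, so the mitochondrially encoded list was not tested.

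Gene symbols were matched by Ensembl identifier to the mouse reference annotation, which is on another build and was used only for names and for which exons of a transcript are coding; 31300 of 35981 single identifiers had a symbol. A gene's count was the sum over its exonic parts, so a read that spans several parts enters more than once. Total part counts per library were 189168456 (WT1), 186022084 (WT2), 231312370 (WT3), 255554573 (KO1), 214948912 (KO2) and 233341997 (KO3). The median SE of a gene's log2 fold change was 0.13. Counts of replicate libraries differed by far more than sampling noise (chi-square per gene 75.9 to 219), so no library was counted as a duplicate.

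Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr defaults, quasi-likelihood fit and test, KO against WT, all 6 libraries, no covariates), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Exon usage was tested with diffSpliceDGE in edgeR on parts kept by filterByExpr in genes with at least 2 such parts, and genes were summarised by Simes' method. The 29 gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01), of which 27 had enough tested members; the list of sex-linked transcripts had 1 tested member. Library levels of lists are medians of log2(CPM / mean WT CPM) with 0.1 CPM added. Shares of counts in a block of exons were compared with exact two-sided permutation tests in SciPy 1.17.1. Intervals of list medians are 95% bootstrap intervals over members from 2000 resamples. The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined.

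The rule named Cd2bp2; the 10 genes with the largest rises and the 10 with the largest falls among genes past the test, with a mean log2 CPM of at least 1 and groups that do not overlap, leaving out unnamed genes and erythroid and sex-linked genes; up to 3 members with the smallest p of each list; and, for exon usage, the part with the smallest p of the 10 genes with the smallest Simes p, of Vegfa, and of podocyte and actin genes past the test. Other members of a list that passed were named as well. The covered fractions of Prm1 and the levels of Col1a1 and Col3a1 were chosen for the report after their values were seen.

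The tests were tested on simulated counts with 200 changed features. For KO against WT gene counts (19491 genes), edgeR recovered 35.8% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 97.0% of those changed 4-fold, with 21 false calls among 159. For exon usage (233865 parts), diffSpliceDGE recovered 0%, 29.9% and 84.8% of parts changed 1.5-fold, 2-fold and 4-fold, with a median p of 0.684 for parts of unchanged genes. Of its 162 calls 76 were on changed parts and 86 on unchanged parts of changed genes, with 0 in unchanged genes. A test with the gene total as offset, added for the low recovery, recovered 26.9%, 85.1% and 100%. Of its 346 calls 141 were on changed and 205 on unchanged parts, 2 of these in unchanged genes. In simulation a call thus marked the gene more surely than the part. The exon simulation gave all parts the same dispersion, not fitted to the spread in these data. A split of the real libraries that mixed WT and KO called 38 parts in 22 genes, so this may not carry over.

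The alternatives were RLE normalization, no filter, at least 1 CPM in 3 libraries, a replicate block, leaving out each library, DESeq2 1.42.0, limma-voom, only parts that overlap no other gene, a minimum change of 1.5-fold with glmTreat, camera with an estimated correlation, fry, and for exons limma-voom diffSplice, at least 10 counts in 3 libraries and a total count of at least 10. Those added after seeing the data were the longest exonic part of each gene alone, leaving out WT3 and KO3 together, and the gene total as offset. Pseudocount alternatives were not run because the files hold counts. Tables were handled in Python 3.11.15 with pandas 2.3.3 and NumPy 2.4.6, and figures drawn with matplotlib 3.10.9.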

Results

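The series compared podocytes, the epithelial cells that form the kidney's filtration slits, labelled as CD2BP2 knockout with podocytes labelled as wild type. CD2BP2 is a GYF domain protein of the U5 small nuclear ribonucleoprotein, a part of the spliceosome, and the study's title names alternative splicing and podocyte integrity as its subjects. Polyadenylated RNA was sequenced in 3 libraries labelled knockout (KO) and 3 labelled wild type (WT). The deposited tables held read counts for exonic parts, which are stretches of exon bounded by every annotated exon edge, and the total part counts ranged from 186022084 to 255554573 per library. The labels name podocytes as the source, while their treatment text describes bone marrow macrophages. In the WT libraries the slit diaphragm gene Nphs1 stood at 2902 ± 121 CPM (counts scaled to library size; SD, n = 3) and the macrophage gene Lyz2 at 42.5 ± 6.34 CPM (SD, n = 3). The labels do not state that the libraries came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Adjusted p-values for genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

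The first question was how far the targeted transcript was reduced. Cd2bp2 (ENSMUSG00000042502; chromosome 7, 134335174 to 134339514, NCBIM37) fell from 61.2 ± 0.56 CPM in WT to 48.9 ± 1.93 CPM in KO (SD, n = 3 each), a log2 fold change of -0.32 with an SE of 0.05 (edgeR adjusted p = 0.0297). The labels place the downstream loxP site after exon 3 of 7 and give no exon for the upstream site. Exons 1 to 3 stood at 65.2% of the WT level in KO, and exons 4 to 7 at 82.9%, so the transcript was reduced but not lost in the libraries labelled KO. The share of Cd2bp2 counts in exons 1 to 3 was 16.6 ± 0.807% in WT and 13.6 ± 0.528% in KO (SD, n = 3 each; exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 samples allow). The fall no longer passed the edgeR test without WT1 (adjusted p = 0.0963), WT2 (0.146), WT3 (0.0606), KO1 (0.106) or KO2 (0.0737). Its adjusted p ranged from 4.0e-06 to 0.146 over 15 alternatives, with a lower level in KO in each of them. For exon usage, no Cd2bp2 part passed diffSpliceDGE in edgeR, nor did the gene pass its Simes test. Part 6, which is exon 3, had an adjusted p of 0.0491 in edgeR with the gene total as offset, a test added after seeing the data.

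**Figure D1:**
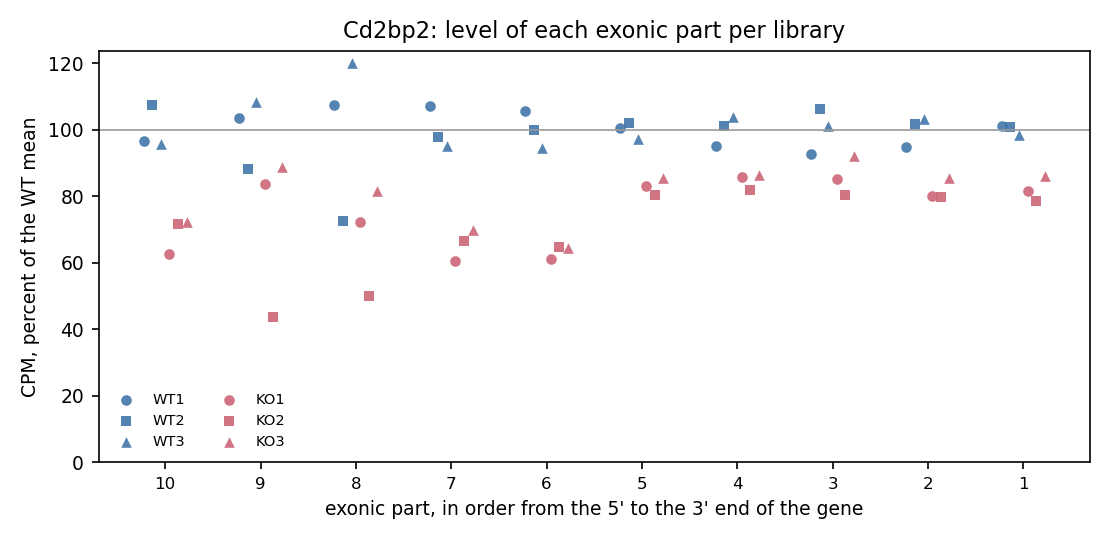
Level of each exonic part of Cd2bp2 in each library, as a percent of the mean WT CPM (vertical axis), with the parts in order from the 5′ to the 3′ end of the gene (horizontal axis). Blue points are the WT libraries and red points the KO libraries; the parts of exons 1 to 3 (10 to 6) together stood at 65.2% of the WT level in KO, and those of exons 4 to 7 (5 to 1) at 82.9%.

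The second question was which genes differed between KO and WT. The largest rise was that of Prm1, which encodes a sperm nuclear protein, from 0.0661 ± 0.0531 CPM in WT to 64.1 ± 39.0 CPM in KO (SD, n = 3 each; log2 fold change 9.83, SE 0.71, edgeR adjusted p = 0.00554). Its 261-base exonic part (chromosome 16, 10796719 to 10796979) had 3102, 2452 and 7406 counts in KO1, KO2 and KO3, which covered 41.0%, 92.7% and 41.4% of its bases. In WT3, 12 counts covered 58.2% of it. In each KO library 100% of the bases of the other part of the gene were covered. The chemokine gene Cxcl10 rose from 4.11 ± 1.17 to 46.0 ± 27.1 CPM, Pamr1 from 17.9 ± 1.61 to 153 ± 45.9 CPM and the tetraspanin gene Tspan32 from 5.55 ± 0.278 to 36.9 ± 0.781 CPM. The inducible heat shock genes Hspa1b and Hspa1a fell by 2.78 and 2.60 on the log2 scale, Hspa1b from 600.4 ± 35.4 to 87.2 ± 44.1 CPM, and the anion transporter gene Slc26a7 fell from 47.3 ± 4.08 to 9.97 ± 0.803 CPM. Hspa1a and Hspa1b are near-identical copies, so the division of reads between them is uncertain. Cxcl10 did not pass without WT1 (adjusted p = 0.0787), WT2 (0.121), WT3 (0.0650) or KO2 (0.0648), and Hspa1b did not pass without WT1 (0.0696), WT2 (0.0943) or KO2 (0.0660). Of 19742 genes tested with edgeR, 666 changed, of which 319 rose and 347 fell, and 194 of them changed at least 2-fold, 144 upward and 50 downward.

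The remaining genes of the largest rises were Crygn (log2 fold change 4.65), Tex45 (3.86), Sorcs1 (3.36), Lrtm2 (3.02), the succinate receptor gene Sucnr1 (2.86) and Adamts8 (2.81). The remaining largest falls were Cyp26a1, which encodes a retinoic acid hydroxylase (-4.72), the histone gene Hist1h1d (-2.22), Slc10a6 (-2.18), Dlk2 (-2.13), the heat shock gene Hspa1l (-2.05), the calcium channel subunit gene Cacna2d2 (-1.90) and Fkbp5, which encodes an immunophilin (-1.72). Their edgeR adjusted p-values ranged from 0.00713 for Hspa1l to 0.0476 for Fkbp5. Tspan32 and Slc26a7 stayed past the test in each alternative run. Tspan32 lies within 20 Mb of Cd2bp2 on chromosome 7. Of 70 named genes past the test besides Cd2bp2, 11 passed in each of the 6 fits with a library left out, namely Col1a2, Crygn, Dnajb1, Hspa1l, Icam1, Nfkbie, Pamr1, Prm1, Slc26a7, Timp1 and Tspan32. Another 18 passed in 0 of them, namely Avpr2, Bcl6, Cd151, Col4a5, Ctss, Hist1h1d, Krt7, Lrtm2, Lsm4, Notch2, Nphs1, Npnt, Phgdh, Spi1, Tnfaip3, Tyrobp, Vcam1 and Vegfa. A further 20 passed in 1 of them, 8 in 2, 4 in 3, 6 in 4 and 3 in 5. The count of changed genes fell whichever library was left out. It was 39 without WT1, 31 without WT2, 254 without WT3, 75 without KO1, 109 without KO2 and 251 without KO3. Without both WT3 and KO3, an alternative chosen after seeing the data, it was 98. Each of these fits held fewer libraries, and whether that alone lowered the count was not tested.

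**Figure D2:**
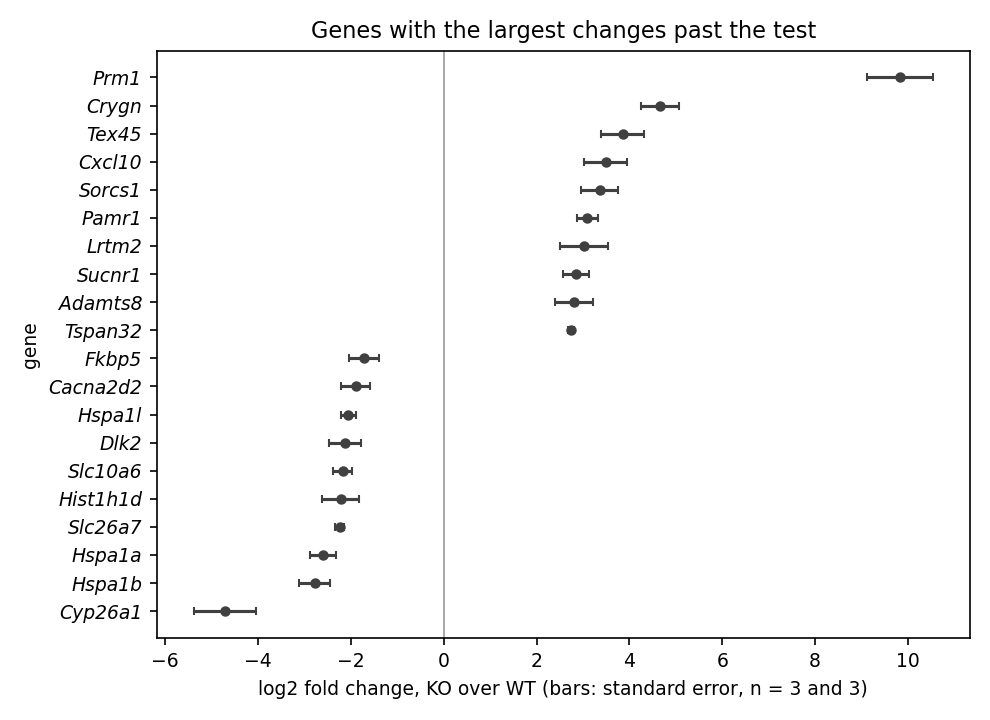
Log2 fold change of KO over WT (horizontal axis) for the 10 genes with the largest rises and the 10 with the largest falls past the test (vertical axis). Points are edgeR estimates and bars are standard errors over 3 KO and 3 WT libraries; Prm1 lies at 9.83 and Cyp26a1 at -4.72.

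Among 30 slit diaphragm and podocyte identity genes, Nphs1, which encodes nephrin, fell by 0.53 on the log2 scale (SE 0.08, edgeR adjusted p = 0.035) to 2014 ± 192 CPM in KO (SD, n = 3), and the peptidase gene Dpp4 fell by 0.69 (adjusted p = 0.0108). Npnt, which encodes the basement membrane protein nephronectin, rose by 0.58 (adjusted p = 0.0297), and the other 27 genes did not pass. Adjusted over the list alone, 2 rose and 8 fell. The list's median log2 fold change was -0.11, or -0.18 without WT3 (camera adjusted p = 0.00235, and adjusted p = 0.604 with an estimated correlation). Against the WT mean, its library medians were 0.034, 0.064 and -0.095 in WT1, WT2 and WT3. They were -0.074, -0.229 and -0.155 in KO1, KO2 and KO3, so KO1 lay above WT3. Of 28 glomerular basement membrane and integrin adhesion genes, the collagen gene Col4a5 (log2 fold change -0.39), Lims1 (-0.33) and the tetraspanin gene Cd151 (-0.23) fell and none rose, and 1 rose and 6 fell when adjusted over the list alone. With a library left out Col4a5 and Cd151 passed in 0 of 6 fits and Lims1 in 1, that without KO3. That list's camera adjusted p was 0.00269, with an adjusted p = 0.595 with an estimated correlation. The fall of Nphs1 did not pass without any 1 of the 6 libraries left out in turn (adjusted p WT1 0.107, WT2 0.15, WT3 0.0619, KO1 0.0588, KO2 0.0959, KO3 0.0674), and its adjusted p ranged from 1.6e-06 to 0.15 over 15 alternatives.

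Of 22 genes of VEGF and angiopoietin signalling, Vegfa, the main endothelial growth factor gene of podocytes, fell from 2010 ± 158 to 1171 ± 156 CPM (SD, n = 3 each; log2 fold change -0.78, SE 0.11, edgeR adjusted p = 0.0301), and the prolyl hydroxylase gene Egln3 rose by 0.94 (adjusted p = 0.0207). Adjusted over the list alone, the same numbers passed, 1 upward and 1 downward. The Vegfa fall did not pass without any 1 of the libraries (WT1 0.0833, WT2 0.125, WT3 0.0606, KO1 0.0769, KO2 0.0548, KO3 0.0519; adjusted p 2.2e-08 to 0.125 over 15 alternatives). Of 46 regulators of the actin cytoskeleton, Palld, which encodes the actin-binding protein palladin, fell by 0.77 (adjusted p = 0.0219) and no other passed, also when adjusted over the list alone. Palld passed in 2 of the 6 fits with a library left out, and Egln3 in 3.

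Among 28 proteins of the U5 particle and the tri-snRNP, the transcripts of Prpf8 and Snrnp200, which encode the U5 scaffold protein and its helicase, rose from 453 ± 8.89 to 610.4 ± 10.8 CPM and from 281 ± 9.76 to 378 ± 2.83 CPM (SD, n = 3 each). Their log2 fold changes were both 0.43 (edgeR adjusted p = 0.0147 and 0.0166), Lsm4 rose by 0.39, and the other 25 did not pass. Adjusted over the list alone, 4 rose and none fell, and the list's median was 0.00 (camera adjusted p = 0.166). Of 36 core spliceosome genes, Smndc1 rose by 0.40 (adjusted p = 0.0269), and adjusted over the list alone 1 rose. None of 57 SR protein, hnRNP and kinase genes passed with edgeR or limma-voom, against 24 at an unadjusted p under 0.05 and 15 with DESeq2 (2 higher, 13 lower). Adjusted over the list alone 5 fell, with a median log2 fold change of -0.15 (camera adjusted p = 2.2e-06, and adjusted p = 0.604 with an estimated correlation). In KO1, KO2 and KO3 the median against WT was -0.115, -0.254 and -0.079, the reverse of the order of the proximal tubule markers (0.47, 0.85 and 0.23). The rise of Prpf8 did not pass without WT1 (adjusted p = 0.0546), WT2 (0.0943) or KO1 (0.0596), and that of Snrnp200 did not pass without these or without KO2 (0.0519); adjusted p for Prpf8 ranged from 8.1e-14 to 0.0943 over its alternatives.

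Among 29 genes of inflammation, 8 rose and 1 fell. Icam1, which encodes a leukocyte adhesion molecule, rose from 24.8 ± 1.13 to 45.9 ± 0.865 CPM (SD, n = 3 each; log2 fold change 0.89, SE 0.05, edgeR adjusted p = 0.00499). Vcam1, Cxcl10, Tnfaip2, and the NF-κB pathway genes Nfkb2, Relb, Nfkbia and Tnfaip3 rose with log2 fold changes from 0.48 for Nfkbia to 3.49 for Cxcl10. The rise of Nfkb2 was 0.21 and did not pass with the longest exonic part of each gene alone, a test added after seeing the data (adjusted p = 0.540; 1.5e-09 to 0.540 over 15 alternatives), nor did it pass without WT1 (0.0643) or WT2 (0.0943). Cxcl12, which encodes a homeostatic chemokine, fell by 1.17. Of the 6 fits with a library left out, Relb and Tnfaip2 each passed in 1 and Nfkbia and Cxcl10 in 2. Adjusted over the list alone, 13 rose and 1 fell. The list's median was 0.61 (camera adjusted p = 3.0e-09; adjusted p = 0.0558 with an estimated correlation; fry adjusted p = 0.00572). Of 22 macrophage and myeloid genes, Lyz2 (1.07), Spi1 (0.89), Tyrobp (0.88) and Ctss (0.76) rose and none fell, and 11 rose when adjusted over the list alone (camera adjusted p = 1.6e-09; adjusted p = 0.556 with an estimated correlation). No interferon-stimulated gene of 30 passed with edgeR or limma-voom (3 at an unadjusted p under 0.05, 2 with DESeq2), also when adjusted over the list alone, and the median was 0.21 (camera adjusted p = 0.0257; adjusted p = 0.715 with an estimated correlation). That median was -0.068 without KO1 (adjusted p = 0.441), 0.19 without WT3 (0.214) and 0.36 without KO2, with adjusted p from 3.6e-06 to 0.441 over 12 alternatives.

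Of 24 immediate early and heat shock genes, 8 fell and none rose. The chaperone genes Dnajb1 (log2 fold change -1.02, SE 0.07, edgeR adjusted p = 0.00554), Hspa1a, Hspa1b, Hsph1 (-1.64), Hspb1 (-1.16), Hspa8 (-1.04) and Hsp90aa1 (-0.93) fell, as did the transcription factor gene Klf6 (-0.77). The value of Hspa8 is that of an aggregate with Snord14e and unnamed genes. Of the 6 fits with a library left out, Hsph1, Hspb1, Hspa8, Hsp90aa1 and Klf6 each passed in 1. Hspa1a and Hspa1b each passed in 3 and Dnajb1 in 6. Adjusted over the list alone, 9 fell. The median was -0.58, or -0.33 without WT2 (camera adjusted p = 6.1e-12, and adjusted p = 0.595 with an estimated correlation). Per library, the list's median against the WT mean was -0.49, 0.29 and 0.069 in WT1, WT2 and WT3. It was -0.85, -0.83 and -0.22 in KO1, KO2 and KO3, so KO3 lay above WT1.

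**Figure D3:**
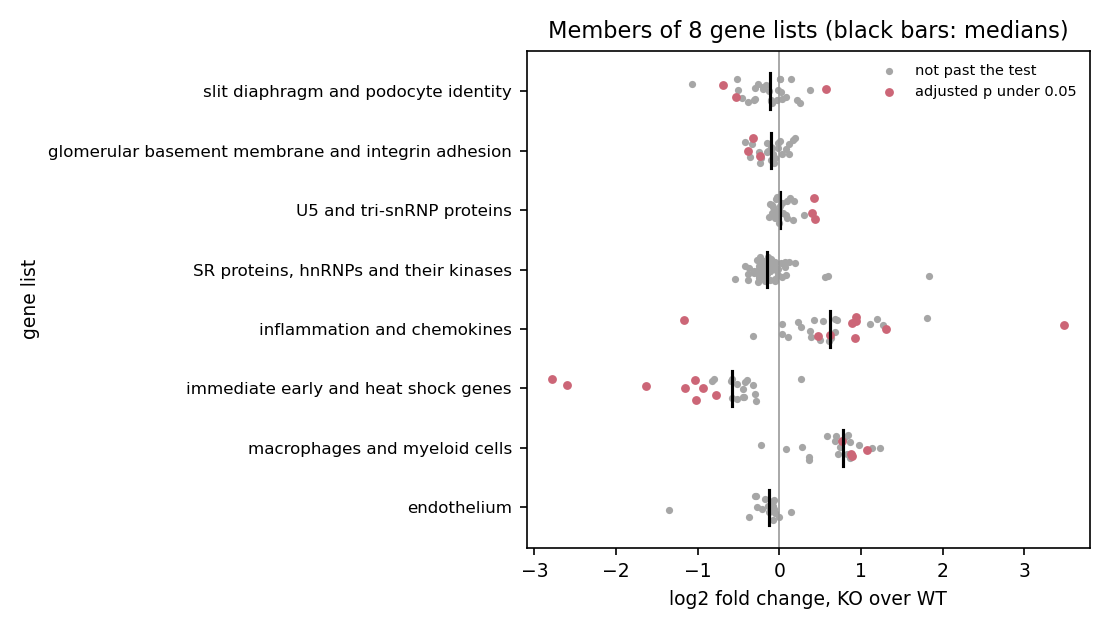
Log2 fold change of KO over WT (horizontal axis) for each tested member of 8 of the gene lists (vertical axis). Each point is a gene, red where its edgeR adjusted p was under 0.05 and grey otherwise, and black bars are list medians, from -0.58 for immediate early and heat shock genes to 0.78 for macrophage and myeloid genes.

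Markers of other kidney cells moved apart from each other. Of 22 proximal tubule genes the transporter genes Slc34a1 (log2 fold change 0.57, edgeR adjusted p = 0.0459) and Slc22a12 (0.52, adjusted p = 0.033) rose, 2 rose when adjusted over the list alone, and the median was 0.55 (camera adjusted p = 1.2e-07; adjusted p = 0.595 with an estimated correlation). Of 23 genes of the loop, distal tubule and collecting duct, the vasopressin receptor gene Avpr2 rose by 1.20 (adjusted p = 0.0489), also when adjusted over the list alone, and the median was 1.61 (camera adjusted p = 6.9e-08; adjusted p = 0.604 with an estimated correlation). Per library, that list's median against the WT mean was 1.11 in KO1, 2.44 in KO2 and 0.178 in KO3. It was 0.085 in WT1, -0.36 in WT2 and 0.184 in WT3, so KO3 was no higher than WT3. Of 12 parietal epithelium genes Pax8 rose by 0.69 (adjusted p = 0.0376), and adjusted over the list alone 3 rose and 1 fell (camera adjusted p = 0.0167; adjusted p = 0.604 with an estimated correlation). Slc34a1, Slc22a12 and Pax8 each passed in 1 of the 6 fits with a library left out, and Avpr2 in 0. None of 17 endothelial, 20 mesangial and smooth muscle, 18 lymphocyte or 6 erythroid genes passed with edgeR or limma-voom, also when adjusted over each list alone with edgeR. At an unadjusted p under 0.05 there were 4, 3, 4 and 1 of these, and DESeq2 called 3, 2, 4 and 1 of them. Their medians were -0.13 (camera adjusted p = 0.00278; adjusted p = 0.604 with an estimated correlation), -0.12 (camera adjusted p = 0.225), 0.77 (camera adjusted p = 0.00113; adjusted p = 0.604 with an estimated correlation) and -0.37 (camera adjusted p = 0.466). Without KO2 the proximal tubule median was 0.34, that of the loop, distal tubule and collecting duct 0.72, and that of the parietal list 0.29. The parietal list was then not called (camera adjusted p = 0.0958), nor was it without WT3 (0.147; 0.0011 to 0.147 over 12 alternatives). The endothelial median was not called without WT3 (-0.11, adjusted p = 0.0752, the highest over 12 alternatives). The lymphocyte median was 0.46 without WT2, 1.32 without WT3 and 0.21 without KO1. Of the sex-linked transcripts Xist alone was tested, with 1201 ± 64.0 CPM in WT and 1169 ± 249.7 CPM in KO (adjusted p = 0.911).

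**Figure D4:**
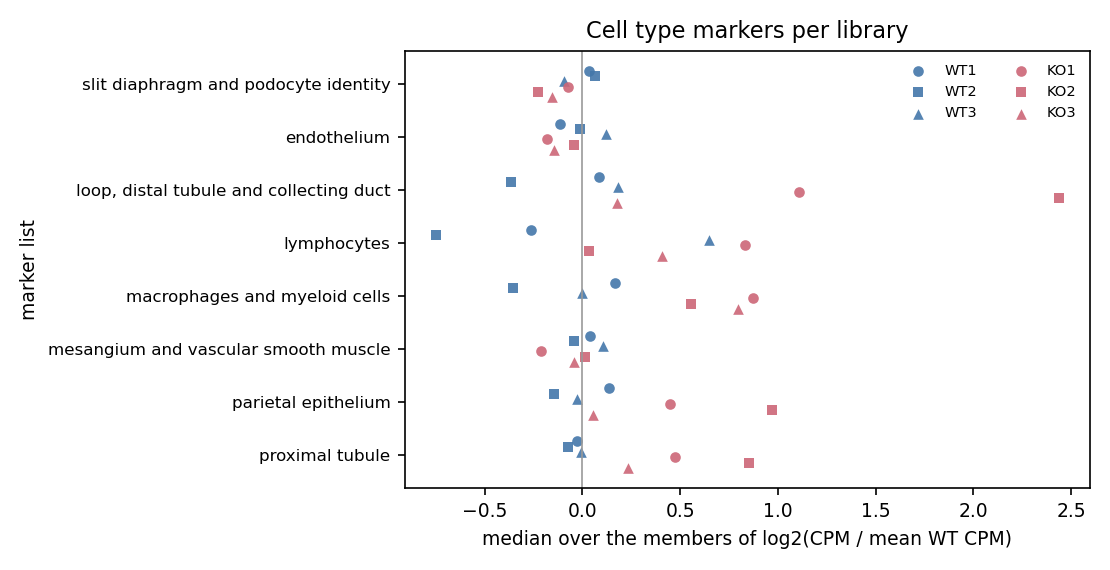
Median over each marker list of log2(CPM / mean WT CPM), with 0.1 CPM added to both (horizontal axis), for each library and list (vertical axis). Blue points are WT and red points KO libraries. The loop, distal tubule and collecting duct markers lie at 1.11, 2.44 and 0.178 in KO1, KO2 and KO3, and at 0.184 in WT3.

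Among 40 genes of podocyte injury, dedifferentiation and fibrosis, the collagen gene Col1a2 rose from 562 ± 89.0 to 2212 ± 184 CPM (SD, n = 3 each; log2 fold change 1.98, SE 0.13, edgeR adjusted p = 0.00554) and the protease inhibitor gene Timp1 from 0.717 ± 0.0299 to 2.45 ± 0.111 CPM. With the longest exonic part of each gene alone, a test added after seeing the data, the rise of Col1a2 was 3.17 (adjusted p = 0.0187). Its parts 3, 4 and 5 fell in usage by 1.09 to 1.14, so the rise was uneven along the gene. The keratin gene Krt7 (-0.48) and the receptor gene Notch2 (-0.31) fell. Adjusted over the list alone, 5 rose and 5 fell (camera adjusted p = 0.166). The collagen genes Col1a1 and Col3a1 had log2 fold changes of 0.18 and 0.08 (adjusted p = 0.752 and 0.924).

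Of 27 genes of the p53 list, Trp53 itself rose by 0.55 and the death receptor gene Fas fell by 0.56 (edgeR adjusted p = 0.0297 and 0.0318), and adjusted over the list alone 1 rose and 2 fell (camera adjusted p = 0.370). With the longest exonic part alone Trp53 rose by 1.05. Trp53 and Fas each passed in 2 of the 6 fits with a library left out. Of 29 genes of the unfolded protein and integrated stress response, the serine synthesis gene Phgdh rose by 0.70, and adjusted over the list alone 1 rose and 1 fell (median -0.21, camera adjusted p = 0.00946; adjusted p = 0.604 with an estimated correlation). Of 24 apoptosis genes the survival genes Mcl1 (-0.43) and Bcl2l1 (-0.63) fell, and 3 fell when adjusted over the list alone (camera adjusted p = 0.225). Mcl1 and Bcl2l1 each passed in 1 of the 6 fits with a library left out. Of 26 genes of cholesterol and fatty acid synthesis the elongase gene Elovl6 rose by 0.92, and adjusted over the list alone 2 rose and 1 fell (median 0.23, camera adjusted p = 0.00333; adjusted p = 0.604 with an estimated correlation). None of 54 nuclear-encoded oxidative phosphorylation genes passed (median 0.13, camera adjusted p = 8.0e-05; adjusted p = 0.604 with an estimated correlation), nor did any of 29 cell cycle genes (median -0.34, camera adjusted p = 0.0170; adjusted p = 0.715 with an estimated correlation), 49 ribosomal protein genes (median -0.05, camera adjusted p = 0.00654; adjusted p = 0.604 with an estimated correlation) or 28 lysosome and autophagy genes (median 0.03, camera adjusted p = 0.394). None of these passed when adjusted over each list alone or with limma-voom either, while at an unadjusted p under 0.05 there were 9, 1, 4 and 7 in that order, and DESeq2 called 3, 0, 0 and 2. These medians leaned on single libraries. The cell cycle median was 0.058 without WT3 (camera adjusted p = 0.971), -0.19 without KO2 (0.306) and -0.33 without KO1 (0.0573). It was -0.55 without WT1 and -0.57 without KO3 (adjusted p 6.8e-06 to 0.971 over 12 alternatives). Without WT3 and KO3 it was -0.17 (adjusted p = 0.0652). Calls ended for the unfolded protein list without WT3 (-0.091, adjusted p = 0.202; 3.4e-06 to 0.324 over 12 alternatives) and for ribosomal proteins without WT3 (-0.036, 0.163; 0.00034 to 0.836). They also ended for oxidative phosphorylation without KO2 (0.042, 0.140; 4.2e-07 to 0.209) and for cholesterol and fatty acid synthesis without KO2 (0.14, 0.0884; 0.00017 to 0.0884). The latter median was 0.14 without WT2 as well. In KO1, KO2 and KO3 the median against WT was 0.077, 0.25 and 0.029 for oxidative phosphorylation and 0.19, 0.37 and 0.060 for cholesterol and fatty acid synthesis, the same order as for the proximal tubule markers (0.47, 0.85 and 0.23). In all, camera with a preset correlation called 17 of 27 lists, while 0 were called with an estimated correlation. The directional test of fry, which asks whether a list's genes move one way, called 1. Its mixed test, which lets genes move either way, passed for most lists, with adjusted p from 1.7e-06 for inflammation to 0.472 for the cell cycle.

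The third question, from the study's title, was which exons were used differently. Several exonic parts that were little used in WT took a larger share of their gene's counts in KO. A 139-base part of Myom2 (chromosome 8, 15058975 to 15059113), a gene of a sarcomere protein, rose from 0.0604 ± 0.00224% to 0.359 ± 0.0357% of the gene's counts (SD, n = 3 each; log2 usage change 2.58, diffSpliceDGE in edgeR, adjusted p = 1.2e-44). Parts also rose in usage in Ahnak (part 24, 1.41), the calcium channel gene Itpr1 (part 29, 2.47) and the methionyl-tRNA synthetase gene Mars (part 23, 2.02). A 2268-base part of Clip1, which encodes a microtubule plus-end protein (chromosome 5, 124063077 to 124065344), fell from 2.5 ± 0.391% to 1.10 ± 0.0794% (log2 usage change -1.18, adjusted p = 4.5e-13).

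Further parts with higher usage in KO lay in the aggregate of Cd247 with Gm16565 (part 1, 3.61), Ttc7 (part 35, 1.81), Sphk2 (part 1, 1.53) and Art3 (part 6, 3.57). The Art3 and Sphk2 parts share bases with another gene, and the Art3 part reaches into Cxcl10, whose own level rose, so the source of their reads is uncertain. The Ttc7 part held 3.97 ± 3.92% of the counts in WT and 14.8 ± 6.11% in KO (SD, n = 3 each), and did not pass with the gene total as offset in edgeR (adjusted p = 0.290), a test added after seeing the data. The usage change of the Ttc7 part ranged from 1.44 to 3.14 with a library left out. A 6-base part of Tbc1d10b (chromosome 7, 134340973 to 134340978), next to Cd2bp2, had counts of 5, 8 and 2 in WT and 73, 42 and 45 in KO (log2 usage change 3.33, adjusted p = 1.0e-07). Of the podocyte and actin lists, part 14 of Dpp4, which shares bases with another gene, fell by 0.73 (adjusted p = 0.00212), and part 7 of the tropomyosin gene Tpm1 fell by 0.60 (adjusted p = 0.0127). The Tpm1 fall passed in 1 of the 6 fits with a library left out, that without KO3 (adjusted p 4.8e-05, and 0.189, 0.277, 0.149, 0.162 and 1.00 without WT1, WT2, WT3, KO1 and KO2), and the Dpp4 fall did not pass without WT2 (0.194) or KO2 (0.198).

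Of 236061 parts tested in 15145 genes with edgeR's diffSpliceDGE, 148 in 72 genes changed in usage, 96 higher and 52 lower in KO, and 58 genes passed the gene-level Simes test. Which direction held more calls depended on the setting, with 79 higher and 96 lower without KO3, 186 and 223 with limma-voom diffSplice, and 171 and 144 with the gene total as offset. Of the 148 parts, 136 (91.9%) belonged to some and not all of the annotated transcripts of their gene, against 75.2% of the parts tested. Aggregates of joined genes held 40 of the 148, against 17293 of the 236061 tested, and 18 against 8636 shared bases with another gene. A part of an aggregate is compared with the transcripts of all joined genes, and a joined gene's change in level can appear as changed usage. These shares thus do not measure splicing alone. The counts varied with the library left out, with 72 parts without WT1, 52 without WT2, 92 without WT3 and 62 without KO1. Without WT2, 35 genes passed. These fits held fewer libraries. In simulated data the test recovered 0% of parts changed 1.5-fold and 29.9% of those changed 2-fold, and 86 of its 162 calls were on unchanged parts of changed genes.

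In Vegfa, an exon of 72 bases (chromosome 17, 46159226 to 46159297, parts 12 and 13) held 4.64 ± 0.13% of the gene's counts in WT and 2.87 ± 0.163% in KO (SD, n = 3 each; exact permutation test, two-sided p = 0.1, the smallest possible). It is exon 6 of transcripts with 7 or 8 exons, in some of which it is coding in the reference annotation, matched by transcript identifier. A transcript with 5 exons holds it as exon 3 with no coding bases given, and another with 8 exons holds only part 13 of it. The level of this exon in KO was 36.0% of WT, and that of all other Vegfa parts together was 59.3%. Among these others, parts 16 to 22 also lay below 59.3%, from 46.3% (part 19) to 49.5% (part 17) of WT. None of parts 16 to 22 passed diffSpliceDGE. Part 12 fell in usage by 0.70 on the log2 scale (diffSpliceDGE in edgeR, adjusted p = 0.0462), while part 13, 54 of the 72 bases, did not pass (-0.69, adjusted p = 0.0669). The gene-level Simes test did not pass either (adjusted p = 0.130). Part 12 did not pass without WT1 (0.509), WT2 (0.267), WT3 (0.615), KO1 (0.308) or KO3 (0.458). It had an adjusted p of 1.5e-05 with the gene total as offset, a test added after seeing the data, and adjusted p ranged from 1.5e-05 to 0.767 over 12 alternatives.

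**Figure D5:**
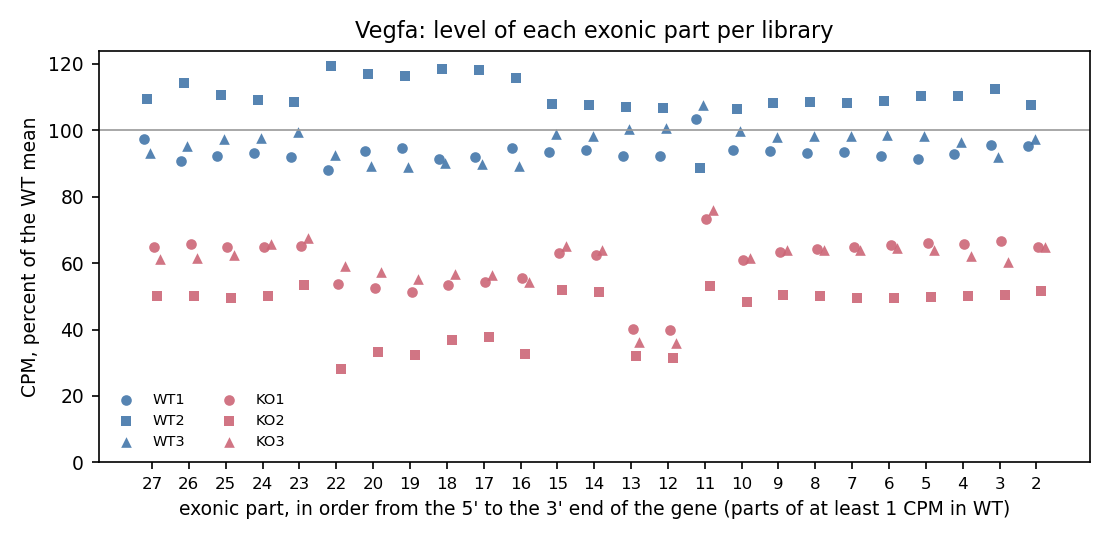
Level of each exonic part of Vegfa in each library, as a percent of the mean WT CPM (vertical axis), in order from the 5′ to the 3′ end (horizontal axis), for parts of at least 1 CPM in WT. Blue points are WT and red points KO libraries. Parts 12 and 13 together stood at 36.0% of the WT level in KO and all other parts together at 59.3%. Among the others, part 19 stood at 46.3% and part 17 at 49.5%.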

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

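The alternatives chosen after seeing the data were the longest exonic part, leaving out WT3 and KO3, and the gene total as offset. The 70 named genes past the test kept their direction in all 1043 comparisons with an alternative, of the 117 named genes run. Of these 70, leaving out a library took 29 (WT3) to 58 (WT2) below the test, and DESeq2 brought 33 of the others past it. RLE normalization (656), no filter (551), at least 1 CPM (720), limma-voom (491) and unshared parts (543) kept the count of 666 changed genes within 1.5 times. It was 82 with the replicate block (51 rose, 31 fell), 2532 with DESeq2, 28 with glmTreat at 1.5-fold, 424 with the longest exonic part, 98 without WT3 and KO3, and 31 to 254 with a library left out (WT1 39, WT2 31, WT3 254, KO1 75, KO2 109, KO3 251). Fewer libraries were fitted there; otherwise the cause was not tested.

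Cd2bp2 stayed lower but not past the test with the replicate block (-0.32, adjusted p = 0.0893), the longest exonic part (-0.27, 0.0546) and without WT3 and KO3 (-0.36, 0.0705), and with a library left out ranged from -0.36 to -0.31 (edgeR adjusted p 0.0457 to 0.146). The same-numbered WT and KO libraries had correlations of 0.11, -0.06 and 0.16 in their deviations. That of WT3 with KO3 (0.16) was the highest of any WT and KO pair. WT1 correlated no better with KO1 (0.107) than with KO2 (0.107). WT3 (-40.9) and KO3 (-30.9) stood apart from the other libraries (7.93 to 24.2) on the second principal component (21.9% of the variance). The numbers thus gave no uniform pairing, and whether WT3 and KO3 share a batch was not tested. With the replicate block 17 lists, 129 parts and 58 genes with changed usage were called, among them 101 of the 148 parts and 46 of the 58 genes, and part 12 of Vegfa (adjusted p = 0.767) and part 7 of Tpm1 (0.104) did not pass.

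The 17 shifted lists became 0 with an estimated correlation and 1 with the directional test of fry, and 12 to 18 with a library left out. The 148 parts became 409 with limma-voom diffSplice, 83 with unshared parts and 315 with the gene total as offset, and 52 to 175 with a library left out (WT1 72, WT2 52, WT3 92, KO1 62). The 58 genes became 245, 36 and 102 in the same settings, and 35 (WT2) to 71 with a library left out. Of the calls, 91 parts and 29 genes were shared with the offset test.

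Directions reversed, the cause not tested, for 7 genes that did not pass and 2 lists that camera had called. Hbb-bt was 0.21 with the replicate block, 1.67 without WT3, 0.092 with limma-voom and 0.71 without WT3 and KO3. Alas2 was 0.25 without WT3 and Xist 0.12 without KO2, and the interferon-stimulated list's median was -0.068 without KO1 and the cell cycle list's 0.058 without WT3. With a library left out Hbb-bt ranged from -1.43 to 1.67, Alas2 from -0.54 to 0.25 and these medians from -0.068 to 0.36 and from -0.57 to 0.058. With the longest exonic part Ndufa7 was -0.22, Gabarap -0.15, Rps3 with Snord15b 0.056 and Serpine2 -0.35, and Nfkb2 (0.21), Avpr2 (0.68) and Tsc22d3 (-0.81) moved over 1.5 times and did not pass, while Trp53 (1.05) and Col1a2 (3.17) moved over 1.5 times and passed. At 186022084 to 255554573 part counts per library, diffSpliceDGE recovered 0% of exon changes of 1.5-fold in simulation and the gene total as offset 26.9%.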

Other observations

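The tests of tubule carry-over, podocyte share, testis RNA, the full Prm1 transcript with KO2 apart, 3′ bias, genome position and overlapping genes, and the counts over other splits, were chosen after the results were seen; the prediction of the coverage test of an introduced Prm1 sequence was written before its values were seen, but after the counts of its parts, and reading it by bounds was chosen after. The genes named here were also chosen after their values were seen, and no enrichment of them was tested. Per1, a clock gene, fell from 219.5 ± 38.9 to 86.5 ± 18.6 CPM (SD, n = 3 each; log2 fold change -1.34, edgeR adjusted p = 0.0288). Tsc22d3 fell by 1.39 (adjusted p = 0.0449; 0.81 and not passed with the longest exonic part alone) and the repressor gene Bcl6 by 0.55 (adjusted p = 0.0459); Per1 and Tsc22d3, like Fkbp5, are known to be induced by glucocorticoids. The NF-κB inhibitor gene Nfkbie rose from 16.6 ± 1.00 to 52.8 ± 2.52 CPM (log2 fold change 1.67, adjusted p = 0.000818), and the Toll-like receptor gene Tlr2 rose by 1.63 (adjusted p = 0.0115), each higher in 3 of 3 KO libraries. The glucocorticoid target Zbtb16 (-4.74, adjusted p = 0.0675) and the clock gene Dbp (2.15, adjusted p = 0.0640) did not pass.

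The interferon-response genes Gbp2 and Tap1 were high in 1 KO library. Gbp2 stood at 174 CPM in KO1 against 38.0 and 43.0 CPM in KO2 and KO3, and Tap1 at 226 CPM against 42.8 and 63.2 CPM. The haemoglobin gene Hbb-bt was highest in WT3 (24.3 CPM) and KO3 (13.6 CPM), and at most 4.62 CPM in the other libraries.

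Levels of tubule and myeloid markers were higher in KO in the list medians. For the loop, distal tubule and collecting duct list, KO3 (0.178) was no higher than WT3 (0.184). A lower share of podocytes, with the other cells in unchanged proportions, would raise the markers of every other cell type alike. The endothelial median had an upper bound of -0.070, below the lower bound of 0.50 for the proximal tubule, which goes against that case. These bounds are over list members, not libraries, and 4 of the 17 endothelial genes are in another list. A lower podocyte share together with other changes stays open. Uneven carry-over of tubule fragments may account for the loop, distal tubule and collecting duct markers, whose medians differed by 2.26 on the log2 scale between KO2 and KO3; the most abundant was Umod, at 591 CPM in KO2 and 88.2 CPM in KO3. If such fragments also carried the myeloid markers, these would be higher in KO2 too, but their median in KO2 lay below that in KO3 (difference -0.24), with Lyz2 at 86.3 and 97.8 CPM. None of the 22 myeloid, 23 loop or 22 proximal tubule genes is in another list, though 19, 16 and 21 of them stood at 1 CPM or more in WT, and genotype remains an untested explanation for the myeloid rise.

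Prm1 had 46183 counts in the KO libraries and 42 in WT. RNA of testis cells would bring other abundant spermatid transcripts, but Prm2, Tnp1 and Tnp2 held 0.0043% of the Prm1 counts. The full annotated transcript would be covered at such depth, as 12 counts in WT3 covered 58.2% of its 261-base part, but 3102 counts in KO1 and 7406 in KO3 covered 41.0% and 41.4%, which goes against it as the main source in these libraries; in KO2 (92.7%) it stays open. An introduced sequence holding part of Prm1, such as an untranslated region in a transgene, is a candidate source that cannot be told apart from a shortened transcript of the gene itself, and its test asked for the coverage over the KO libraries pooled, which lies from 92.7% to 100% against a bound of 95%. The labels name a Cre transgene, MxCre, only in their text on macrophages.

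Changed exon usage was weighed against 3 technical explanations. A 3′ bias that differs between groups would shift usage along genes by about the size of the called changes (median 1.18 on the log2 scale), but the 3′ end and the 5′ end of genes differed by 0.018. Variants of the strain around the targeted gene would place calls near it, but 1.35% of the called parts lay within 20 Mb of Cd2bp2. There 2 of 5748 tested parts were called (0.035%), against 0.063% elsewhere (Fisher's exact test, two-sided p = 0.592). This bears on the flanking region as a main source only, and variants elsewhere in the genome were not tested. With only parts that overlap no other gene, 55.4% of the called parts were also called, so annotated overlapping exons are not the source for those. The share itself says little, as only 40 of the 148 called parts lay in aggregates and 18 shared bases with another gene. Most calls thus lay in parts that this filter did not remove, though such calls can still be lost as the set of tested parts changes. Reads of unannotated transcripts were not tested. The bounds for these tests were set when part of the values had been seen. Genotype stays open as an untested explanation.

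Other splits of the 6 libraries into groups of 3 number 10 with the real one, too few for a share under 0.05. The real split called 666 genes and the highest other 2, and the real split was the 1 with as many. Each other split mixed WT and KO libraries, so a difference between WT and KO added to the spread within its groups. Their low counts thus do not show how many calls would arise without such a difference. For lists the real split called 17 and the others 8 to 15, so camera with the preset correlation called lists in every split. For exonic parts the real split called 148 and the highest other 38, and for genes with changed usage 58 and 22. Again 1 split, the real one, gave as many. Within 20 Mb of Cd2bp2, 22 of 435 genes were called (5.06%), against 3.34% elsewhere (Fisher's exact test, two-sided p = 0.0586). These 22 include Cd2bp2 itself, Tspan32 and Cd151. Whether variants of the strain near the targeted gene account for such calls was not tested.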
